A study of Mus musculus with 2 samples.

How the data were processed

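The series measured H3K4me2, a histone mark found at active and poised promoters and at enhancers, by chromatin immunoprecipitation and sequencing in whole mouse liver at embryonic day 15.5. There was 1 group with 2 biological replicates. Replicate 1 pooled the livers of 78 embryos of both sexes and replicate 2 those of 62. Per the labels, the sequenced fragments were 300 to 500 bp.

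The authors deposited 4 peak lists, each given as start and end in bp on the mm10 assembly. A list was called from each replicate's filtered alignments, a pooled list from the alignments of both replicates, and a replicated list was derived from the pooled list and the 2 replicate lists. Replicate 1 combined 2 technical replicates and replicate 2 had 1. The signal value that the authors give per peak is an enrichment from their peak caller whose scale is not stated, so it was used only to rank peaks within a list. The deposited lists also give the −log10 of the q value per peak, which was used for a stricter threshold. The aligner, the peak caller, their versions and the rule behind the replicated list are not given in the sources used here. The lists give no number of reads, so the depth of each sample is unknown. Intervals on shares of peaks or genes are Wilson 95% intervals and cover counting error only. An input control is named in the labels, but only calls made by the authors were analysed, so no background was measured in a control sample.

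The replicated list was used for every call. Each replicate's own list gave the replicate values, printed as mean ± SD with n = 2. Peaks on the assembled chromosomes were used for all gene and sequence results. No peaks overlapped within a list, so merging left their number unchanged. Coordinates are printed counting from 1.

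Genes and transcription start sites (TSSs) came from the GENCODE M21 annotation, and sequence from GRCm38.p6, the same coordinates as mm10. The annotation held 21911 protein-coding genes on the assembled chromosomes, with 93423 TSSs, and 132721 TSSs over all 55413 genes. A promoter peak overlapped the window of 1 kb either side of any annotated TSS of the gene. Location was called in the order promoter, exon, intron and intergenic, over all annotated genes. The H3K4me2 extent of a gene was the number of base pairs covered by peaks within 5 kb either side of its TSS, at the TSS with most covered bases. These base pairs could belong to several peaks, including peaks that did not cover the TSS or that lay at a neighbouring gene. A distal peak lay over 2.5 kb from every annotated TSS, and was counted for each gene whose body lay within 50 kb. A peak could therefore count for several neighbouring genes, and a region called as several peaks counted several times.

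The definitions, tests, gene lists and alternatives were fixed before the data were examined, except where stated. The 17 gene lists covered fetal and adult hepatocytes, erythroid, haematopoietic stem and progenitor, myeloid, megakaryocyte, lymphoid, endothelial, stellate and biliary cells, genes of other tissues, Hox clusters, housekeeping, cell cycle, and olfactory and vomeronasal receptors. Of 348 gene names in the lists, 1 (Ahsp) had no match, and Erg and Hoxa9 stood in 2 lists each. The genes named in the text are, in each list, the 3 members with most covered base pairs and the first 3 by symbol without a promoter peak. The 10 protein-coding genes whose TSS lay in the widest peaks were added, and, in lists past the threshold for distal peaks, the 3 members with most. The Alb to Afp region and both globin clusters were always described, each with 40 kb of flank. Other genes that the text names were chosen after their values were seen, and the text says so.

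Sharing between replicates was an overlap of at least 1 bp by bedtools 2.31.1, set beside 100 circular shifts of a list along each chromosome. Promoter peaks of a list were compared with those of all other protein-coding genes by Fisher's exact test. Extent was compared with 10000 random lists of the same size drawn from genes with a promoter peak, and distal peaks with 10000 random lists of protein-coding genes, which permutes list membership. The smallest p of the random lists was 0.0002. Lists were contrasted directly by Fisher's exact test for promoter peaks and by a permutation test of 100000 resamples for distal peaks. All tests were two-sided. Benjamini-Hochberg adjustment was over the 17 lists, or over the 4 direct contrasts, with a threshold of 0.05. Genes are not independent replicates, and no test between the 2 samples was possible.

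Motif matches on both strands of distal peaks were divided by matches of the reversed, not complemented, motif, which has the same base composition. This ratio was divided by the same ratio in intervals of equal width shifted by 20 kb that touched no peak. Intervals came from 1000 bootstraps of blocks of 1 Mb. The 12 motifs were set in advance. The rule that a ratio needs at least 50 matches in each of its counts was added after the counts were seen, and it left HNF1, with 15 matches in peaks, without a ratio. For 5 motifs, matches per kb were compared between distal peaks near fetal hepatocyte genes and near erythroid genes by permuting genes 100000 times.

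The alternatives set in advance were each replicate's own list, the pooled list, a −log10 q of at least 5, larger and smaller windows, other overlap rules, matched backgrounds and other control intervals. Promoter backgrounds were matched on the observed over expected CpG ratio within 500 bp of the TSS in 10 bins. They were drawn from all protein-coding genes, receptor genes included. Distal backgrounds were matched on gene length and on local TSS number, in 5 bins each. The local TSS number was that of annotated TSSs of any gene within the gene body and 50 kb either side. Alternatives added later are named in the closing section.

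The tests were tested on simulated data. Among 20000 genes, 100 lists of 25 genes were planted at once at a promoter share of 0.95 against 0.68, beside 100 unchanged lists. Of the planted lists 62% were recovered, and 5% of the unchanged lists were called. An unadjusted p under 0.05 by Fisher's exact test was given for 11% of the unchanged lists. A planted 2-fold number of distal peaks was recovered in 55% of 20 lists, with 0% of 20 unchanged lists called. For a 2-fold extent these shares were 95% and 5%. A planted 3-fold contrast was recovered in 92% of simulations, and 3% of unchanged ones were called. A planted motif ratio of 1.77 gave 1.80, with an interval of 1.69 to 1.92, and without a planted motif it was 0.986 (0.916 to 1.06). Only the GATA motif was simulated, with the same base composition in peaks and controls. The effect of a difference in composition was therefore not tested. The overlap count equalled that of bedtools, 638 of 3000 simulated peaks.

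Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0, samtools 1.23.1 and matplotlib 3.10.9. The text descriptions deposited with the lists hold no measurements and were used only for the steps above.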

Results

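H3K4me2 was mapped in whole mouse liver at embryonic day 15.5, an age at which the organ holds both hepatoblasts and most of the blood-forming cells of the fetus. There was 1 group of 2 biological replicates, each a pool of livers. The labels give no treatment and no second tissue, so the comparisons were between replicates, between parts of the genome and between groups of genes. The authors' lists held 48873 peaks for replicate 1, 60020 for replicate 2, 56700 for both pooled and 40178 replicated peaks. The replicated peaks covered 60.4 Mb, or 2.22% of the assembled chromosomes, with a median width of 1015 bp. The number of reads behind the lists is unknown.

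Peaks that overlapped promoters held most of the marked sequence. Of the replicated peaks, 19573 (48.7%, 95% interval 48.2 to 49.2%) overlapped the window of 1 kb either side of a TSS. Counted at their full width, these peaks held 70.7% of the covered base pairs. Introns held 26.0% of peaks, sequence between genes 18.3% and exons 7.01%. In circular shifts of the peaks, promoters held 10.2% ± 0.336 (SD over 100 shifts), so that promoters were 4.79-fold over the shifts and intergenic sequence was at 0.378-fold. Promoter peaks had a median width of 1909 bp, against 609 bp in introns and 687 bp between genes. The promoter share in the replicates' own lists was 42.8% ± 2.73 (SD, n = 2), below that of the replicated list in each.

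A promoter peak was present at 14873 of 21911 protein-coding genes (67.9%, 67.3 to 68.5%), and at 68.2% ± 0.871 (SD, n = 2) in the replicates. In all, 14729 genes carried a promoter peak in both replicates' own lists, 83 only in that of replicate 1 and 353 only in that of replicate 2. The widest peaks over a TSS included those of genes of the red cell membrane skeleton. Ank1, which encodes the ankyrin of the red cell skeleton, lay under a peak of 28400 bp (chromosome 8, 23032923 to 23061322). Zfpm1, a cofactor of GATA1, lay under 23644 bp (chromosome 8, 122280176 to 122303819) and Rbm38 under 22121 bp (chromosome 2, 173017880 to 173040000). The widest peaks in the lists of replicates 1 and 2 were 20986 and 19993 bp. The peaks at Ank1, Zfpm1 and Rbm38 were therefore not single peaks of these widths in either replicate. A single peak of 16965 bp on chromosome 8 spanned the TSSs of Junb, Prdx2, Rnaseh2a and Gm49661. Epb41, which encodes protein 4.1 of the red cell membrane, shared a peak of 15313 bp with Gm10300, and Rhof lay under 15244 bp. Ank1 and Zfpm1 belong to the erythroid list described next.

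The question of which cell types' genes carried the mark in the whole organ was addressed with lists of marker genes. The share of each cell type in the livers was not measured, so differences between lists can reflect cell numbers as well as marking. Erythroid genes had promoter peaks at 28 of 29 members, 96.6% against 67.8% of other genes. The exception was Slc25a37, the mitochondrial iron importer mitoferrin 1, with no covered base pair within 5 kb of its TSS in the replicated list or in either replicate. All of the 32-base words around that TSS (100%) occur elsewhere in the genome as well. Haematopoietic stem and progenitor genes had promoter peaks at 20 of 22 members (90.9%), with none at Mpl, the thrombopoietin receptor, or at Slamf1, although Mpl had one in replicate 2. All 25 housekeeping genes and all 26 cell cycle genes had one. By Fisher's exact test the adjusted p was 0.00143 for erythroid, 0.0441 for stem and progenitor, 0.000635 for housekeeping and 0.000542 for cell cycle genes. Against a background matched on promoter CpG the stem and progenitor call ended, with an adjusted p of 0.0540 under permutation of list membership, as it did with the pooled list and with either other promoter window. Housekeeping and cell cycle genes were expected at 96.6% and 98.2% there, so that lists at 100% could not pass and that background did not test them. The share in the replicates was 96.6% ± 0 (SD, n = 2) for erythroid and 93.2% ± 3.21 (SD, n = 2) for stem and progenitor genes.

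Fetal hepatocyte genes had promoter peaks at 26 of 30 members, 86.7% against 67.9% of other genes, and 85% ± 7.07 (SD, n = 2) in the replicates. This list missed the threshold, with an adjusted p of 0.0567 by Fisher's exact test. It passed with replicate 2's own list at 90%, adjusted p = 0.0209 by the same exact test, and with replicate 1's own list it was at 80%. Its members without a promoter peak were Alb, Fga, Serpina1b and Ttr, the last of which falls outside the rule for named genes. Serpina1b and Ttr had a promoter peak in replicate 2, and Fga had 2441 bp covered within 5 kb of its TSS.

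Adult hepatocyte genes had promoter peaks at only 12 of 30 members (40%; 45% ± 2.36, SD, n = 2). Pah, which encodes phenylalanine hydroxylase, Glul, glutamine synthetase, and Ass1 of the urea cycle were marked, while Baat, Cps1 and Cyp1a2 were not. Muscle genes had promoter peaks at 7 of 24 members (29.2%; 35.4% ± 2.95, SD, n = 2), among them Mylpf, Myl7 and Tnni3 but not Acta1, Actc1 or Myf5. Genes of lung, pancreas and intestine had them at 10 of 24 members (41.7%; 47.9% ± 8.84, SD, n = 2), with none at Cdx1, Cdx2 or Cpa1 in the replicated list and a peak at each of these in replicate 2. These 3 lists lay below other genes, with adjusted p values of 0.00715, 0.000872 and 0.0202 by Fisher's exact test. Olfactory and vomeronasal receptor genes had a promoter peak at 6 of 1462 members (0.410%, 0.188 to 0.892%) against 72.7% of other genes. For them the −log10 of the hypergeometric p was 752, and Fisher's p was too small for the software to hold. Vmn1r4, Olfr56 and Olfr65 were the receptor genes with most covered sequence within 5 kb of the TSS, and Olfr65 had no promoter peak.

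The other lists did not pass the threshold by Fisher's exact test. Myeloid genes had promoter peaks at 10 of 22 members (45.5%, adjusted p = 0.0627 by the exact test), including Prtn3, Cd68 and Cebpe but not the macrophage genes Adgre1, C1qa and C1qb, of which Adgre1 had a promoter peak in replicate 2. With replicate 1's own list they lay below other genes past the threshold, at 40.9%, exact adjusted p = 0.0312. Lymphoid genes had them at 9 of 20 (45%, exact adjusted p = 0.0795), including Ebf1, Lef1 and Bcl11b but not Blk, Cd19 or Cd3e. Megakaryocyte genes had them at 10 of 16 (62.5%), endothelial genes at 14 of 21 (66.7%), stellate and mesenchymal genes at 16 of 20 (80%) and biliary genes at 10 of 12 (83.3%). Neural genes had them at 19 of 26 (73.1%) and Hox genes at 28 of 39 (71.8%). The adjusted p of these 6 lists ran from 0.470 to 1 in the exact test. With the pooled list, Hox genes lay above other genes past the threshold, at 87.2%. With 1 TSS per gene, an alternative added later, lymphoid genes lay below other genes past the threshold, at 30%.

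A background matched on promoter CpG changed several of these calls, since it set another expected value for each list. It was drawn from all protein-coding genes. The 1462 receptor genes among them, with a median CpG ratio of 0.144, lower the expected share of low-CpG lists. By how much was not measured. Fetal hepatocyte genes at 86.7% lay above 57.6%, and megakaryocyte genes at 62.5% above 37.6%. Neural genes at 73.1% lay below 90.8%, and Hox genes at 71.8% below 92.4%. These 4 lists passed the threshold in that comparison, with adjusted p values of 0.00085, 0.0321, 0.00623 and 0.00085 under permutation of list membership within CpG bins. Myeloid genes at 45.5% lay above 27.3% and endothelial genes at 66.7% above 57%, both on the other side than against all genes, and did not pass (adjusted p = 0.0553 and 0.499 in that permutation). Erythroid genes, expected at 52.9%, endoderm genes, expected at 65.4%, and receptor genes, expected at 10.4%, passed as well. Adult hepatocyte genes at 40% lay above an expected 31.9%, with an adjusted p of 0.491 in that permutation. Muscle genes and stem and progenitor genes no longer passed. The endoderm call ended with replicate 2's own list, the pooled list and a window of 2.5 kb.

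**Figure D1:**
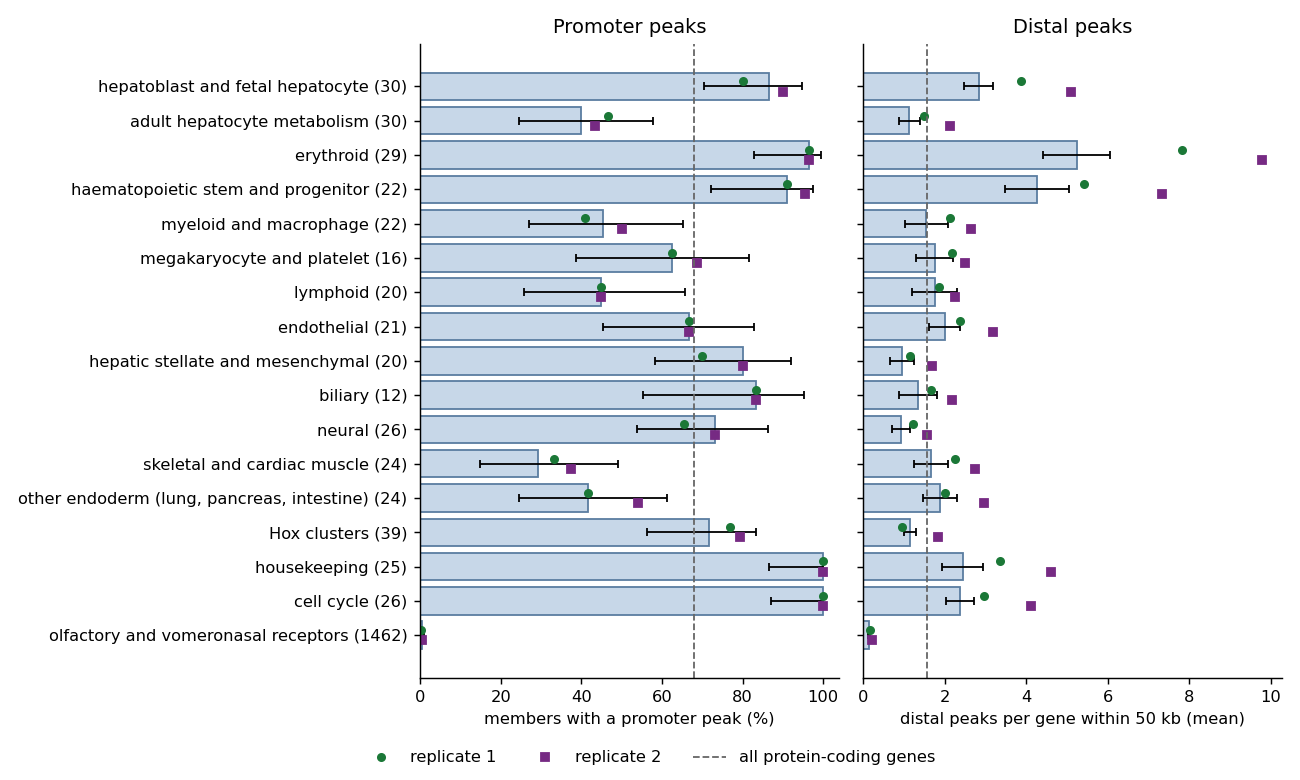
The share of each list's members with a promoter peak in percent and the mean number of distal peaks per gene within 50 kb, with the number of members in brackets. Bars show the replicated list with Wilson 95% intervals on the left and the standard error over genes on the right, circles and squares show the replicates' own lists, and the dashed line shows all protein-coding genes (67.9% and 1.57); erythroid genes stood at 96.6% and 5.24.

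The mark was broadest at erythroid genes. Among members with a promoter peak, the median covered by peaks within 5 kb either side of the TSS was 7237.5 bp for erythroid genes, against 2920 bp for all 14873 marked genes. Slc4a1, the anion exchanger of red cells, had 9875 bp covered (9724 ± 56.6, SD, n = 2). The transcription factor genes Nfe2 and Tal1 had 9862 and 9815 bp. Stem and progenitor genes had a median of 5502.5 bp, led by Lmo2 (8488 bp), Runx1 (8117 bp) and Meis1 (7794 bp), transcription regulators of blood stem cells. Fetal hepatocyte genes had a median of 4398 bp, led by the hepatoblast regulator Prox1 (8224 bp), the fetal growth factor gene Igf2 (6863 bp) and Onecut1 (6250 bp).

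Housekeeping genes, with Hmbs, Rpl13a and Tubb5 the most covered, had a median of 5471 bp. Cell cycle genes, with Cdc6, Rrm2 and Pcna, had 5286.5 bp. Erythroid, stem and progenitor, housekeeping and cell cycle genes each had an adjusted p of 0.00068 under permutation of list membership, the smallest the random lists gave, and fetal hepatocyte genes had 0.00437. Medians in the replicates were 6901.5 ± 26.9 bp (SD, n = 2) for erythroid genes, 5261.5 ± 117 bp for stem and progenitor genes and 3750.5 ± 309 bp for fetal hepatocyte genes.

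Narrow marks were found at genes of mesenchyme, the nervous system and the body axis. Medians were 1693 bp for stellate and mesenchymal genes, 1912 bp for neural genes, 1743 bp for Hox genes and 554.5 bp for the 6 marked receptor genes. Their adjusted p values under permutation of list membership were 0.00807, 0.0204, 0.0017 and 0.00068. Single members stood above their list, such as Reln at 7358 bp, Alcam at 5199 bp, Gfap at 4145 bp and Hoxa7 at 4305 bp. No peak covered a TSS of Gfap itself, so its value came from peaks beside it. The remaining 8 lists lay between 1997 bp for muscle and 2795.5 bp for megakaryocyte genes and did not pass.

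In replicate 1's own list the fetal hepatocyte median was 3532 bp, adjusted p = 0.0946 under the same permutation, and that of receptor genes was 1739.5 bp, adjusted p = 0.229. Adult hepatocyte and myeloid medians passed there at 1505 and 1193 bp, and muscle genes passed in replicate 2's own list at 1409 bp. The fetal hepatocyte call also ended with a window of 2 kb, the stellate call with the pooled list and with a CpG-matched background, and the neural call with the stricter threshold.

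**Figure D2:**
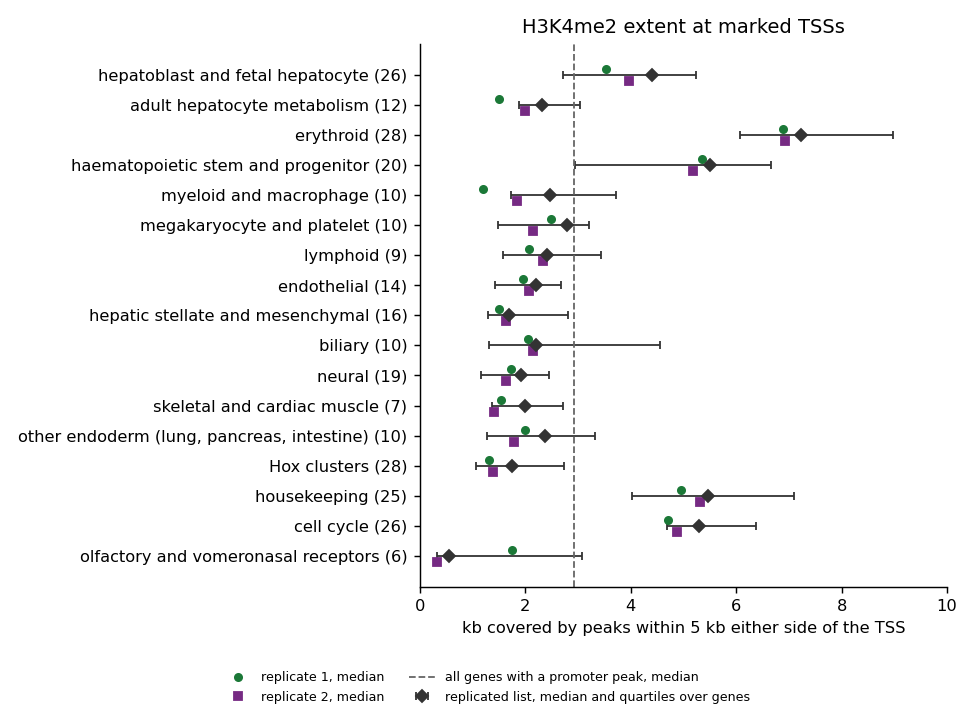
Base pairs in kb covered by H3K4me2 peaks within 5 kb either side of the TSS, for the members of each list with a promoter peak, whose number stands in brackets. Diamonds and bars are the median and quartiles over genes in the replicated list, circles and squares are the medians in the replicates' own lists, and the dashed line is the median of all marked genes; the erythroid median of 7237.5 bp was the highest and the receptor median of 554.5 bp the lowest.

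Distal peaks, which lay over 2.5 kb from every TSS, were most numerous around erythroid and stem and progenitor genes among the lists. There were 16649 of them (41.5% of replicated peaks), or 1.57 per protein-coding gene within 50 kb, and 9686 genes (44.2%) had none. Peaks were counted as called, so a broad region called in pieces counts more than once. The base pairs covered by distal peaks were not compared between lists. Erythroid genes had a mean of 5.24, which was 3.32-fold over random lists. Hbb-bs, the adult beta-globin gene, had 18, the spectrin gene Sptb had 15 and Bcl11a, a regulator of globin switching, had 12. Stem and progenitor genes had a mean of 4.27 (2.72-fold), with 14 around Ikzf1, 10 around Flt3 and 9 around Lyl1.

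Receptor genes had a mean of 0.132 (0.0839-fold). Olfr64, Olfr65 and Olfr66 each had 18, and these genes lie next to the beta-globin cluster. The adjusted p values were 0.0136 for erythroid, 0.0147 for stem and progenitor and 0.0034 for receptor genes under permutation of list membership. Replicate means were higher, at 8.81 ± 1.39 (SD, n = 2) for erythroid and 6.36 ± 1.35 for stem and progenitor genes, where the replicates' own lists held 20565 and 27071 distal peaks.

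Fetal hepatocyte genes had a mean of 2.83 distal peaks (1.81-fold) and missed the threshold at an adjusted p of 0.0552 under permutation of list membership. They passed with each replicate's own list, with the pooled list and with random lists matched on gene length and local TSS number, against which they were 2.08-fold higher. The other 13 lists ran from 0.588-fold for neural to 1.56-fold for housekeeping genes and did not pass, with myeloid genes at 0.979-fold and lymphoid and megakaryocyte genes at 1.11-fold each. Hox genes, at 0.732-fold, were at 0.474-fold in replicate 1's own list with an adjusted p of 0.0313 under the same permutation.

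The fetal and the adult hepatocyte lists differed in a direct contrast. The fetal list mixes transcription factor and plasma protein genes, while the adult list holds mostly enzymes and transporters. The contrast therefore does not separate stage from kind of gene. Promoter peaks were present at 86.7% of 30 fetal and 40% of 30 adult hepatocyte genes, and distal peaks averaged 2.83 against 1.13 per gene. The transcription factor genes Prox1 and Onecut1 of the fetal list were among the marked genes, and the bile acid and drug metabolism genes Baat and Cyp1a2 of the adult list were among those without a promoter peak. Conversely, Alb and Fga of the fetal list had no promoter peak, and Pah, Glul and Ass1 of the adult list had one. The difference in promoter peaks gave p = 0.000368 in Fisher's exact test and that in distal peaks p = 0.00037 in the permutation test, both 0.00074 after adjustment over 4 contrasts. Replicate 1 gave differences of 33.3 percentage points and 2.37 peaks, and replicate 2 gave 46.7 and 2.97. Part of the promoter difference may come from promoter CpG, since the matched lists stood at 57.6% for the fetal and 31.9% for the adult genes. Those lists included receptor genes, so the size of that part is not known. The contrast itself was not matched on CpG. No adult liver was measured.

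Erythroid genes had more distal peaks than fetal hepatocyte genes, 5.24 against 2.83 per gene. The permutation test gave p = 0.00663, adjusted p = 0.00884, and the difference of 2.41 peaks was 3.96 in replicate 1 and 4.69 in replicate 2. Promoter peaks, at 96.6% and 86.7%, did not differ past the threshold (p = 0.353 in Fisher's exact test, the same after adjustment). A cluster such as beta-globin places the same distal peaks near several erythroid genes, so genes were not independent in this contrast. Erythroid genes also had the broadest marks at their TSSs, and broad regions called in pieces would add to their count, which was not tested.

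The globin clusters were densely marked and the albumin region sparsely. The alpha-globin region (chromosome 11, 32236400 to 32337298) held 29 replicated peaks over 40534 bp. Peaks lay just upstream of the adult genes Hba-a1 (32280145 to 32283474) and Hba-a2 (32293560 to 32296289), and a peak of 7424 bp spanned the TSS of Hbq1b (32286077 to 32293500). Further peaks ran through the neighbouring gene Nprl3, which holds the major upstream enhancers of alpha-globin, and up to its own TSS (32265498 to 32270025). The embryonic gene Hba-x had no promoter peak in the replicated list or in replicate 1, and had one in replicate 2.

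The beta-globin region (chromosome 7, 103772524 to 103893216) held 28 peaks over 21372 bp. The adult genes Hbb-bt and Hbb-bs had promoter peaks, with 5597 and 3771 bp covered within 5 kb of the TSS. The embryonic genes Hbb-y, Hbb-bh1 and Hbb-bh2 had none in the replicated list or in replicate 1, while Hbb-y and Hbb-bh2 had one in replicate 2. Intergenic peaks formed a cluster from 103858618 to 103878080, upstream of Hbb-y, where the locus control region of these genes lies. The replicates' own lists held 28 and 43 peaks in this region, and 36 and 48 in the alpha-globin region.

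The Alb to Afp region (chromosome 5, 90420897 to 90548907) held 4 replicated peaks over 1810 bp, and 4 and 6 in the replicates' own lists. Alb, the gene of serum albumin, had no base pair covered within 5 kb of its TSS in the replicated list or in either replicate, and an exonic peak at 90468491 to 90468735. Afp, the gene of the fetal plasma protein alpha-fetoprotein, starts at 90490737 and had a peak downstream of its start, at 90492238 to 90492751. This peak touched the edge of the promoter window of an annotated TSS inside the gene, 1000 bp away. Each replicate's own list held a peak there, which reached the promoter window in replicate 2 and not in replicate 1. The number of peaks per region is a description and was not tested. In a whole organ, few peaks at a region can also reflect few cells that carry the mark.

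**Figure D3:**
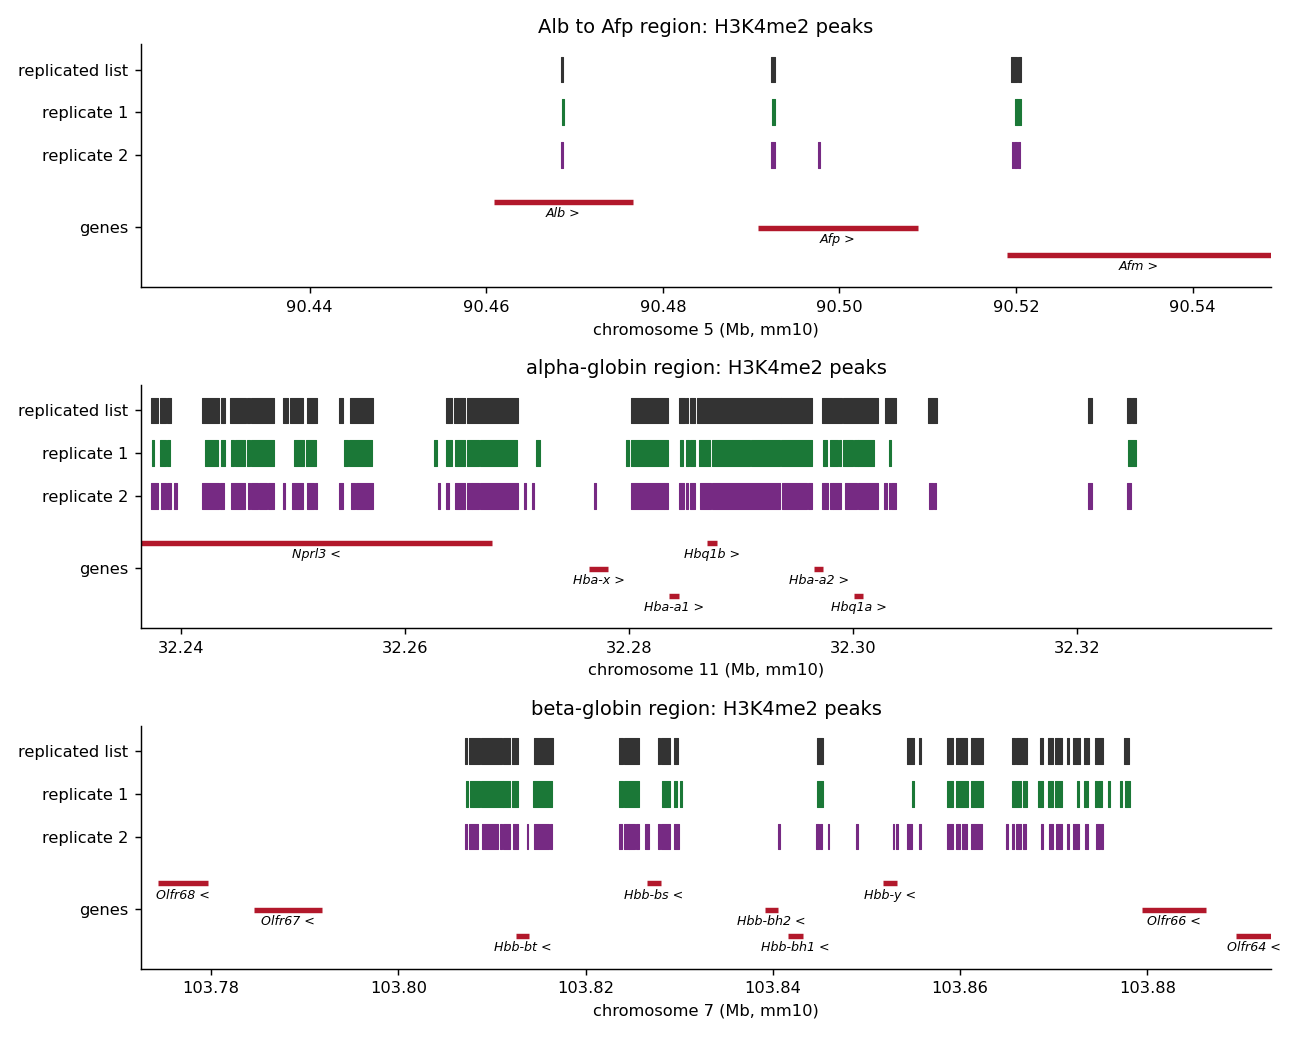
Peaks of the replicated list and of each replicate along the Alb to Afp, alpha-globin and beta-globin regions, each with 40 kb of flank, with the x axis in Mb of the mm10 assembly and gene bodies below (arrows give the direction of transcription). The regions held 4, 29 and 28 replicated peaks, and 4, 36 and 28 peaks in replicate 1 and 6, 48 and 43 in replicate 2.

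Relative to reversed motifs, distal peaks were enriched for 5 of the 12 motifs, those of GATA, FOXA, ETS, HNF4 and NFE2 factors. The GATA motif AGATAA, bound by GATA1 and GATA2 in blood cells, had a ratio of 1.79 (95% interval 1.71 to 1.89) over its reversed motif and shifted intervals. FOXA motifs, bound by pioneer factors of liver, had a ratio of 1.37 (1.27 to 1.49), ETS motifs 1.34 (1.26 to 1.42), HNF4 motifs 1.22 (1.07 to 1.40) and NFE2 motifs 1.17 (1.09 to 1.26). GATA motifs were present in 42.7% of distal peaks and 34.7% of shifted intervals. In the replicates' own lists the GATA ratio was 1.79 and 1.83, and the FOXA ratio 1.42 and 1.39.

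Intervals that held 1 were found for KLF at 1.02 (0.988 to 1.06), for the neural factor motif NEUROD at 1.01 (0.911 to 1.12), for OCT at 1.17 (0.811 to 1.57) and for the muscle factor motif MEF2 at 1.24 (0.954 to 1.62). SOX motifs were at 0.925 (0.871 to 0.980) and CEBP motifs at 0.765 (0.709 to 0.832). HNF1 had too few matches for a ratio, 15 in peaks and 2 in shifted intervals. Distal peaks had 49.2% G and C bases and shifted intervals 45.2%.

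The control by reversed motifs decided some of these values, and the reversed strings of CEBP and OCT hold a CG. Reversed KLF strings, which like the KLF motif can hold a CG, were also denser in peaks. They stood at 0.674 per kb against 0.311 in shifted intervals, and KLF motifs at 0.825 against 0.371. The KLF ratio near 1 therefore cannot show whether KLF sites were enriched. Without the reversed motif, CEBP was at 1.02, SOX at 1.01, NEUROD at 0.947, OCT at 0.982, MEF2 at 0.980 and KLF at 2.22, while GATA stayed above 1 at 1.33. HNF4 was at 1.11 (0.940 to 1.27) in replicate 1's own list, and MEF2, below 1 without the reversed motif, was past 1 with it in replicate 2's own list, in the pooled list and over 5 kb from TSSs.

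**Figure D4:**
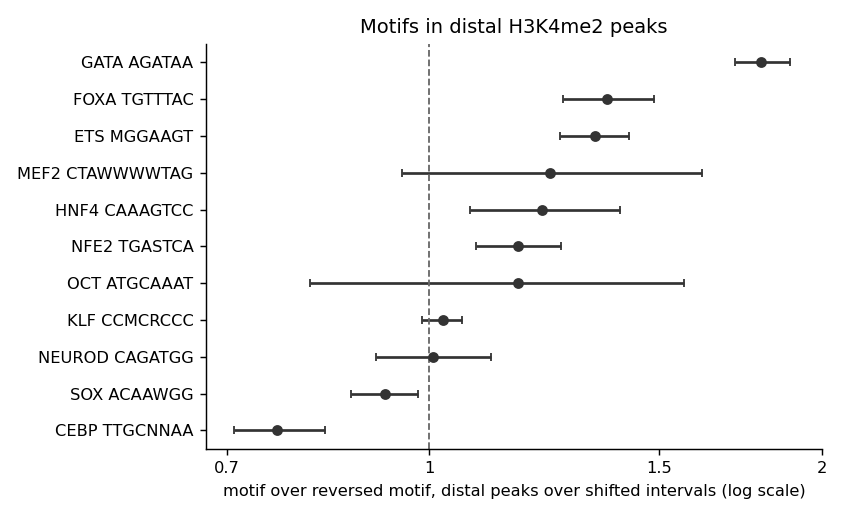
Motif matches in distal peaks over the reversed motif, divided by the same ratio in intervals shifted by 20 kb (log scale), with bars as 95% bootstrap intervals. GATA was the highest at 1.79 and CEBP the lowest at 0.765; the dashed line marks a ratio of 1.

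Distal peaks near the hepatocyte and near the erythroid genes did not differ past the threshold in these motifs. GATA motifs stood at 0.689 per kb in 70 peaks near 26 fetal hepatocyte genes and 0.637 per kb in 139 peaks near 27 erythroid genes. FOXA motifs stood at 0.145 and 0.127 per kb, CEBP motifs at 0.345 and 0.404, and HNF4 motifs at 0.0726 and 0.0354. The adjusted p was 0.678 for HNF4 and 0.908 for the other 3 in the permutation of genes. HNF1 motifs had 0 matches near either list, and HNF4 motifs rested on 4 and 5 matches.

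The replicates shared their strong peaks and differed in weak, narrow ones. Of replicate 1's peaks, 85.5% (85.2 to 85.8%) overlapped a peak of replicate 2, and of replicate 2's peaks 72.9% (72.5 to 73.2%) overlapped a peak of replicate 1. Circular shifts gave 4.24% and 3.65%. Erythroid genes had a promoter peak at 28 of 29 members in each replicate. Shared peaks had median widths of 775 and 794 bp, and the 7071 and 16285 unshared peaks 234 and 208 bp. A −log10 q under 5 was given for 93.1% and 85.3% of the unshared peaks.

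The pooled peaks were split into 10 equal parts by signal value, and all peaks in the 3 highest parts overlapped a peak in both replicates. The share was 95.9% in part 5, 42.4% in part 7 and 4.14% in part 10, and 64.7% over the whole list. The replicated list was made of pooled peaks unchanged in position, 70.9% of them, with a median width of 1015 bp against 238 bp for the 16522 left out. Of the replicated peaks, 36546 (91.0%) overlapped a peak in both replicates, 3558 in 1 replicate and 74 in neither. The base pairs covered in both replicates came to 48.3 Mb of 62.9 Mb covered in either. With 2 samples no difference between replicates was tested, and the share moved from 66.7% to 93.9% of replicate 1's peaks, and from 54.3% to 96.5% of replicate 2's, with the overlap rule and threshold.

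**Figure D5:**
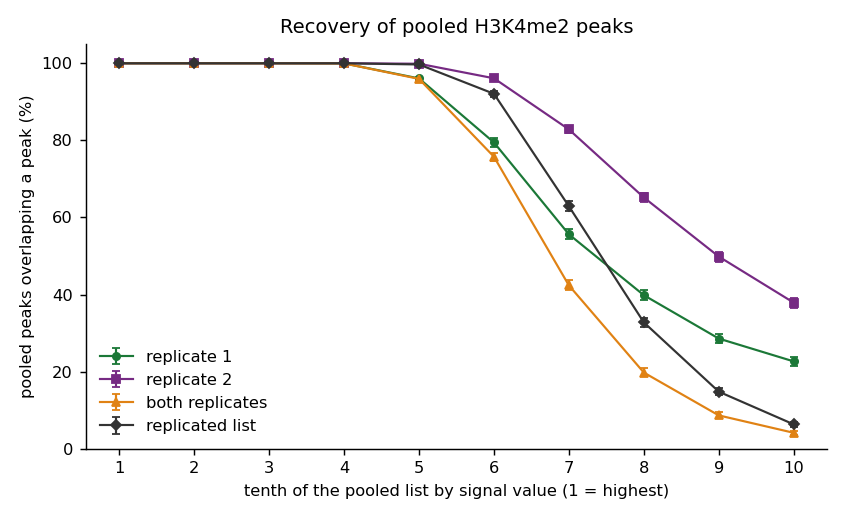
Percent of pooled peaks that overlap a peak of replicate 1, of replicate 2, of both replicates or of the replicated list, for 10 equal parts of the pooled list ordered by signal value (1 is the highest), with Wilson 95% intervals. Recovery in both replicates was 100% in the first 3 parts and 4.14% in the last.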

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

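On sequences outside the assembled chromosomes, which no gene, location or motif result used, the replicated list held 12 of its 40178 peaks. They stood out because they are signal in sequence that those results left out, although the overlaps between lists counted them, and no control sample was at hand to set a background. The lists of replicate 1, of replicate 2 and of both pooled held 14, 14 and 15 such peaks. No explanation was tested for them, and no other result met the limits set for a closer look, since the design has 1 group of 2 samples.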

How the results depend on the processing

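Of 525 recalculated values, 447 kept their side of the threshold or moved by less than the spread, 17 lost a call, 26 gained 1, 7 changed direction with a call before or after and 28 untested values moved. Values that passed neither before nor after count among the 447 whatever their direction. Chosen after seeing the data were 1 TSS per gene, regions with a peak in both replicates, and motif ratios without the reversed motif. The cause was not tested for any change below. The direct contrasts of fetal with adult hepatocyte genes and of hepatocyte with erythroid genes kept their side of the threshold in all 10 recalculations each, none of which matched CpG. Erythroid promoter, extent and distal calls held in every alternative run. No paired analysis was possible because there was 1 group. Sharing between replicates and recovery of pooled peaks cannot be computed without either replicate, and HNF1 had too few matches for a ratio. The unknown depth limits the weak peaks, where the replicates differ most.

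Sharing moved with the overlap rule, for replicate 1's and replicate 2's peaks, to 77.0% and 65.0% at 50% of the peak and to 66.7% and 54.3% at a reciprocal 50%. It was 93.9% and 82.3% at a −log10 q of at least 5, and 92.7% and 96.5% for the 20000 top peaks. Pooled peaks found in both replicates were 52.9% at 50% of the peak and 89.9% at the stricter threshold, where 95.3% were replicated.

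The promoter and intergenic shares of peaks were 40.03% and 19.9% with the pooled list, 51.5% and 17.8% at the stricter threshold, 45.3% and 18.9% with a promoter window of 500 bp and 58.5% and 16.3% with 2.5 kb. Genes with a promoter peak were 69.4% with the pooled list and 69.2% with 2.5 kb.

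Without either replicate the ranges were 40.9 to 44.8% for promoter peaks, 18.1 to 18.8% for intergenic peaks and 67.6 to 68.8% for genes with a promoter peak. Promoter shares by list were 80 to 90% for fetal hepatocyte genes (passing without replicate 1), 41.7 to 54.2% for endoderm genes (lost without replicate 1) and 40.9 to 50% for myeloid genes (passing without replicate 2). Extents were 3532 to 3969 bp for fetal hepatocyte and 319 to 1739.5 bp for receptor genes (both lost without replicate 2). They were 1505 to 1997 bp for adult hepatocyte and 1193 to 1841 bp for myeloid genes (both passing without replicate 2), and 1409 to 1543.5 bp for muscle genes (passing without replicate 1). Distal folds were 1.94 to 1.97 for fetal hepatocyte genes (passing without either) and 0.474 to 0.710 for Hox genes (passing without replicate 2). Motif ratios were 1.11 to 1.15 for HNF4 (lost without replicate 2) and 1.3 to 1.33 for MEF2 (passing without replicate 1).

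With the pooled list, fetal hepatocyte promoters (96.7%) and Hox promoters (87.2%) gained a call, and stem and progenitor (90.9%) and endoderm promoters (50%) lost it. Stellate extents (2080.5 bp) lost a call, and muscle extents (1554 bp), the fetal hepatocyte distal fold (1.93) and MEF2 (1.32) gained 1. At the stricter threshold myeloid promoters (36.4%) gained a call and neural extents (1932 bp) lost it. With a promoter window of 500 bp, stem and progenitor genes (86.4%) lost the call and myeloid genes (40.9%) gained it. With 2.5 kb, fetal hepatocyte genes (96.7%) gained it, and stem and progenitor (90.9%) and endoderm genes (50%) lost it. With 1 TSS per gene, myeloid (36.4%) and lymphoid genes (30%) passed, and with regions of both replicates myeloid genes (40.9%) did.

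Against a CpG-matched background the direction changed for adult hepatocyte (40%, expected 31.9%), megakaryocyte (62.5%, 37.6%), neural (73.1%, 90.8%) and Hox promoters (71.8%, 92.4%). It also changed, with no call before or after, for myeloid (45.5%, 27.3%) and endothelial promoters (66.7%, 57%). Fetal hepatocyte promoters (86.7%) gained a call, and stem and progenitor (90.9%), muscle (29.2%), housekeeping (100%) and cell cycle promoters (100%) and stellate extents (1693 bp) lost it; the expected 96.6% and 98.2% left housekeeping and cell cycle genes no room to pass. In a window of 2 kb, fetal hepatocyte extents (2870 bp) lost a call and myeloid extents (988 bp) gained it. Matched on gene length and local TSS number, the fetal hepatocyte distal fold was 2.08 and passed. With controls shifted by 50 kb, KLF passed at 1.05, and OCT (0.896) and NEUROD (0.973) fell below 1 with no call. Over 5 kb from TSSs, MEF2 passed at 1.43. Without the reversed motif, CEBP (1.02), SOX (1.01) and NEUROD (0.947) changed sides of 1, as did OCT (0.982) and MEF2 (0.980) with no call before or after, and KLF passed at 2.22.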

Other observations

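The limit of 5 kb for a broad peak and the reading of the CpG-matched background were chosen after the values were seen; both tests of repeated sequence were set after their patterns were seen and before repeated sequence was counted. Repeated words were counted first over all reference sequences, then over the primary assembly alone, since alternative loci repeat it by design; the readings were the same and the latter values are given.

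Peaks of at least 5 kb numbered 1034, or 2.57% of replicated peaks and 11.4% of the covered base pairs. They overlapped the window of 1 kb either side of a TSS at 1189 protein-coding genes (5.43%, and 3.62% and 3.07% in the replicates' own lists). Erythroid genes had such a peak at 19 of 29 members (65.5%; 48.3% and 44.8% in the replicates' own lists), among them Ank1, Zfpm1 and Tal1. Stem and progenitor genes had it at 9 of 22 (40.9%), housekeeping genes at 8 of 25 (32%) and cell cycle genes at 8 of 26 (30.8%). In the lists of replicates 1 and 2 these shares were 36.4% and 27.3%, 20% and 12%, and 15.4% and 19.2%. These shares are descriptions, since the limit was set after the wide peaks of these lists were seen. Fetal hepatocyte genes had it at 3 of 30 (10%), and none of the adult hepatocyte, myeloid, megakaryocyte, lymphoid, endothelial, neural, endoderm or Hox genes did.

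Genes that encode no protein had a peak near any of their TSSs less often. Protein-coding genes were 21911 of 55413 genes but held 93423 of the 132721 TSSs. They therefore had more windows per gene in which a peak could count, and the shares below were not corrected for this. A peak within 1 kb of a TSS was present at 18.9% of long intergenic RNA genes, 39.6% of antisense genes and 3.23% of processed pseudogenes. Away from TSSs of coding genes these shares were 12.8%, 12.8% and 2.28%. Among microRNA genes the share was 18.0%, and 6.67% away from coding TSSs. By chromosome, promoter peaks were present at 81.6% of protein-coding genes on chromosome 12, 49.6% on X and 2.19% (4 of 183) on Y. None of these shares was tested.

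Slc25a37, a gene of red cell iron uptake, had no peak within 5 kb of its TSS while the other 28 erythroid genes had promoter peaks. A candidate explanation is sequence repeated elsewhere in the genome, where reads have no single place. Of the 32-base words within 5 kb of its TSS, 100% occur more than once in the primary assembly, against a median of 5.34% and a highest value of 43.6% at the other erythroid genes. This goes with the explanation, although the sources used here do not say how reads with several places were treated. A true lack of the mark at this gene stays open and no biological explanation was tested.

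Olfactory and vomeronasal receptor genes almost never had a promoter peak, and repeated sequence could in principle hide them as well. Among the 875 receptor genes with under 20% repeated words, 3 had a promoter peak (0.343%, 0.117 to 1.00%), which argues against repeated sequence as the cause for these genes. Low CpG content is not enough either, since lists matched on promoter CpG had a mean share of 10.4% against 0.410% here, the latter below all random lists (adjusted p = 0.00085 in the permutation). Receptor genes in more repeated sequence were not resolved by this test. No biological explanation was tested, since no tissue that expresses these receptors was measured.

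Adult hepatocyte genes had promoter peaks less often than other genes, and low CpG content of their promoters may account for this. Lists matched on promoter CpG had a mean share of 31.9%, against 40% for the adult list, with an adjusted p of 0.491 under permutation of list membership. The median observed over expected CpG ratio was 0.256 for adult and 0.365 for fetal hepatocyte genes. Fetal hepatocyte genes lay above their own matched lists, 86.7% against 57.6%. All these matched lists were drawn with the receptor genes included, whose median ratio was 0.144 and of which 0.410% had a promoter peak. This lowers the expected shares by an amount that was not measured. The comparison therefore cannot decide whether CpG content accounts for either share. The age of the tissue stays open as an explanation for the adult genes, since no adult liver was measured.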
